A study of Mus musculus with 6 samples.

How the data were processed

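Total RNA of 6 fetal mouse lungs at stage E18.5, 3 labelled Nfib f/f and 3 labelled Nfib f/f with Dermo1-Cre, was extracted with TRIzol, purified on RNeasy columns and turned into biotin-labelled cRNA for Affymetrix arrays, per the labels' protocols. The submitters' processing notes name MAS5 and affy, without versions. The deposited values are log2 signals: raised to the power of 2, their mean after trimming 2% at each end was 150.04 to 150.05 on every array, and between 4.93% and 6.49% of the values of an array lay below 0. How the signals were scaled beyond this is not given in the sources used here. The values were used as deposited, with no offset. Values far below 4 on this scale carry much noise, since MAS5 subtracts a background for each probe set.

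The table held 45101 probe sets, of which 64 Affymetrix control probe sets were left out. Of the rest, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 had none; probe sets with several or none were tested but not named. For 34741 of the single-symbol probe sets the gene identifier was found in a RefSeq gene table (GRCm38.p6), which was used only for names. No coordinates of probes were given and none are printed. For each gene the probe set with the highest mean over the 6 arrays stood for it. Of the 120 named genes past the threshold, 53 had other tested probe sets; 22 of these had another one called the same way, none had one called the other way, and 3 had one of the opposite sign.

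Probe sets were kept when their mean over all 6 arrays reached the 40th percentile of the 45037 probe sets that were not controls, which left 27022. They were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, no covariates), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Residual degrees of freedom were 4, and the prior added 5.32. Gene lists were compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over the 26 lists with at least 5 tested genes. Of 587 entries in 33 lists, 557 were matched to a probe set, 9 of them through an older symbol or a synonym; the other 30 were not analysed here. The sex chromosome list only described the arrays. The lists share some genes, such as Scnn1g, Dusp1, Pdpn and Npnt. Nfib was also compared by an exact permutation test.

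The test, the lists and the rule for named genes were fixed before the data were examined. The text names the 12 largest rises and the 12 largest falls among called genes whose groups did not overlap, leaving out RIKEN, Gm, LOC and EST names, every list member past the threshold, the nuclear factor I genes, and 2 to 4 genes of each list with the smallest unadjusted p. Myl7 and Alb, members of the cardiac and liver lists named for their levels on single arrays, were picked after their values were seen, and Xist and Eif2s3y only describe the arrays.

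The choices varied were quantile normalization, scaling to a common median, offsets of 1 and 64 on the linear scale, no filter and a filter at the 60th percentile, no intensity trend, array weights, the replicate number as a block, each array left out in turn, an adjusted p of 0.10, a 1.5-fold minimum, 1 probe set per gene, camera with an estimated correlation, fry, and the mean of a gene's probe sets. Covariates for fetal sex, for the mean of the cardiac muscle list (the cardiac score) and for the difference between 3' and 5' control probe sets of Actb and Gapdh were added after seeing the data.

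The fit was tested on simulated data with the means and spread of these arrays and 200 changed probe sets, of which those that passed the filter were counted. The genes of the pericyte list were also lowered, and their calls count among all calls. Noise was drawn independently for each probe set, without the variation that genes share on real arrays. The rates that follow therefore need not hold for the real arrays. For 3 against 3 simulated arrays and 27022 probe sets, 42 of 46 probe sets with a 4-fold change, 36 of 43 with a 3-fold change, 22 of 45 with a 2-fold change and 1 of 50 with a 1.5-fold change were recovered, and 8.55% of all calls fell on unchanged probe sets. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.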

Results

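Gene expression was measured in fetal mouse lungs at stage E18.5, shortly before birth, on Affymetrix mouse arrays with 1 array per animal. The 6 animals formed 2 groups of 3, which the labels call biological replicates. All carried 2 floxed alleles of Nfib, the gene of the transcription factor nuclear factor I B. The labels give the Dermo1-Cre transgene to 3 of them and no Cre to the other 3. Dermo1-Cre expresses Cre recombinase from the Dermo1 (Twist2) locus and is used to delete floxed genes in mesenchyme. The comparison asks how loss of mesenchymal Nfib bears on cell proliferation and epithelial differentiation in the maturing lung. The groups are named here as labelled, Cre-labelled and control-labelled lungs, because the genotypes could not be checked against the arrays. Every array had the same trimmed mean signal, between 150.04 and 150.05, and its median log2 signal lay between 4.81 and 5.03. Across all probe sets, which are not independent replicates, arrays of the same group correlated at 0.940 to 0.950 and arrays of different groups at 0.931 to 0.949. Differences are log2 differences, Cre-labelled minus control-labelled, with the standard error of the limma fit on 3 against 3 arrays. The number of arrays limits their precision.

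Nfib signal was higher in the Cre-labelled lungs. The brightest Nfib probe set measured 10.24 ± 0.07 (SD, n = 3) in control-labelled and 11.30 ± 0.17 (SD, n = 3) in Cre-labelled lungs, a 2.07-fold difference (log2 difference 1.05 ± 0.12 SE, limma adjusted p = 0.0049). On the single arrays it read 10.24, 10.32 and 10.17 in control-labelled and 11.24, 11.16 and 11.49 in Cre-labelled lungs. In an exact permutation test of this probe set p was 0.10, two-sided, the smallest value that 3 against 3 arrays allow. Of 7 Nfib probe sets, 6 were tested and 5 of these rose, each by at least 2.05-fold. The sixth read 9.55 ± 0.13 (SD, n = 3) in control-labelled and 9.45 ± 0.22 (SD, n = 3) in Cre-labelled lungs (limma adjusted p = 0.71). The seventh lay below the filter, at 2.63 ± 1.41 and 4.05 ± 0.45 (SD, n = 3 each). The sources used here do not say where these probes lie relative to the deleted part of the gene, so the probe sets cannot check the labels, and every direction given here rests on the labels as deposited. The weakest call of the 5 (adjusted p = 0.0497) held in 9 of 18 alternative fits (adjusted p 0.0036 to 0.23) and was lost in 5 of the 6 fits without 1 array, all but that without Cre-labelled replicate 2.

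None of the 11 tested probe sets of the other nuclear factor I genes passed the threshold. The brightest probe set of Nfia had a log2 difference of 0.36 ± 0.12 SE (limma adjusted p = 0.15), which stayed positive in all 18 alternative fits. A dimmer Nfia probe set had a larger difference, 0.86 ± 0.29 SE (adjusted p = 0.15), and passed in 2 of 18 alternative fits, with the replicate block and without Cre-labelled replicate 2 (adjusted p 0.029 to 0.36 over all 18). The values were -0.07 ± 0.19 SE for Nfic (adjusted p = 0.88) and 0.04 ± 0.14 SE for Nfix (adjusted p = 0.90), and these changed sign in 2 alternative fits each. Adjusted over the list alone, 1 probe set for each of the 4 genes, 2 rose.

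**Figure D1:**
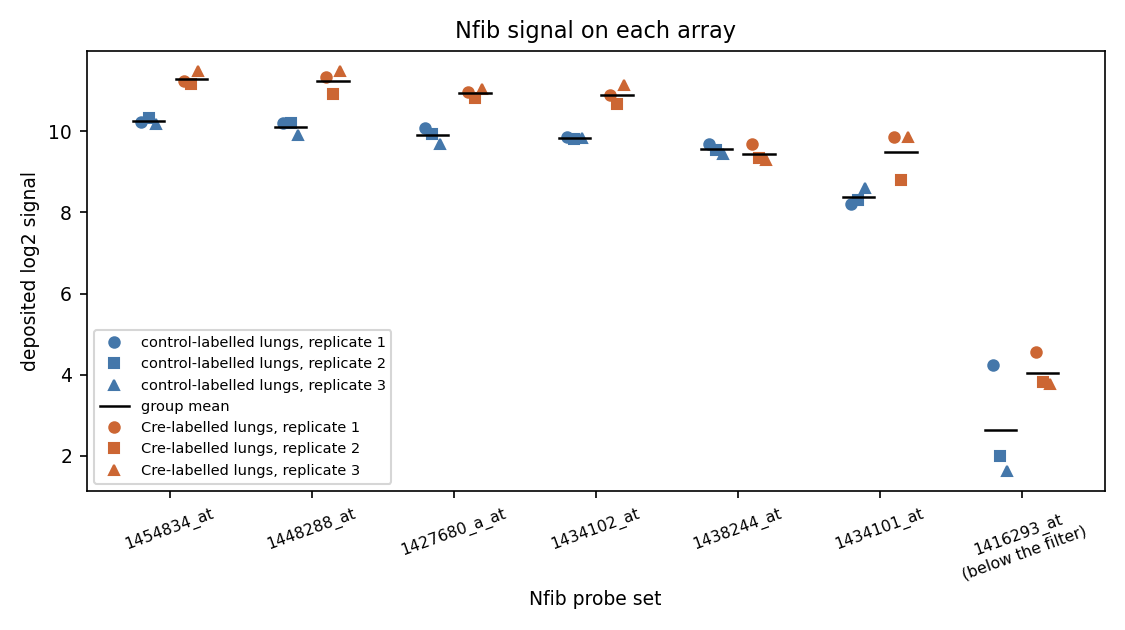
Deposited log2 signal of the 7 Nfib probe sets (horizontal axis) on each of the 6 arrays, with marker shape for the replicate, colour for the labelled group and a bar for each group mean. In 5 of the 6 tested probe sets all Cre-labelled arrays lay above all control-labelled arrays; the exception overlapped, and the seventh probe set was below the filter.

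Across the array, 963 of 27022 tested probe sets (3.56%) passed an adjusted p of 0.05, 380 higher and 583 lower in Cre-labelled lungs. Counted by the 1 probe set that stood for each gene, 246 genes rose and 390 fell among 12826 genes with a tested probe set. On these values, used without an offset, 201 called probe sets fell and 61 rose by at least 2-fold. Among the 12 largest falls, Fmo2, a flavin monooxygenase abundant in lung, had a log2 difference of -2.67 ± 0.27 SE (limma adjusted p = 0.0038), and with an offset of 64 on the linear scale it had the largest fall of these 12 (-2.43). Others were in the chitinase-like gene Chil1, S100g, the capillary carbonic anhydrase gene Car4, Clec3b, which encodes tetranectin, the muscle phosphoglycerate mutase gene Pgam2, Gdpd2 and the angiotensinogen gene Agt. The other 4 of the 12, Chad, which encodes a cartilage matrix protein, Inmt, an N-methyltransferase, the metallothionein gene Mt3 and Phgr1, averaged below the level required by the filter in Cre-labelled lungs. Among the 12 largest rises, Pam, which encodes the enzyme that amidates peptide hormones, had a log2 difference of 1.70 ± 0.19 SE (adjusted p = 0.0049; 1.31 with the offset of 64, then the largest of these 12), and Synpo2, an actin-binding protein gene, one of 1.56 ± 0.20 SE. Others were in Ap1s3, the metalloproteinase gene Adamts18, Igdcc4, Slitrk6, Hpse2, the protease gene Cym and Lin7a, and in Pdzrn4, Far2, a fatty acyl-CoA reductase gene, and Arpp21, these 3 with control-labelled means below the filter level. All 24 stayed past the threshold with the offset of 64, but with it 4 of the 12 falls and 3 of the 12 rises were at least 2-fold, and Chad went from -2.82 to -0.65 and Pdzrn4 from 3.08 to 0.65. Sizes and ranks of genes near the floor therefore depend on the offset. In the 6 fits without 1 array, Adamts18, Arpp21, Lin7a, Pgam2 and Phgr1 passed the threshold in 1 fit each. Pdzrn4 and Inmt passed in 2, Mt3 in 3, and Far2 and Clec3b in 4, and the rest of the 24 passed in all 6. Over 17 alternative fits Pgam2 passed in 7 (limma adjusted p 0.021 to 0.25). One of the other 2 Synpo2 probe sets had the opposite sign without passing the threshold. Without control-labelled replicate 1, 2 or 3 the count fell to 411, 314 and 314 probe sets, and without Cre-labelled replicate 1, 2 or 3 to 354, 495 and 425. It was 171 without an intensity trend in the variance, 587 with fetal sex as a covariate, 215 with the mean of the cardiac muscle genes as a covariate and 2120 at an adjusted p of 0.10.

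Of 26 gene lists fixed before the data were examined and large enough to test, 16 moved against the other genes in limma's camera test with a preset correlation of 0.01, 2 higher and 14 lower in Cre-labelled lungs. None held with a correlation estimated for each list, where the adjusted p of these 16 lay between 0.20 and 0.55. The estimates ran from -0.07 for the lymphatic list to 0.89 for skeletal muscle, and the cell cycle list had 0.26. All other alternatives for the lists but fry kept the preset correlation, so they do not check that choice. The other 9 splits of the 6 arrays into 3 and 3 called 4 to 13 lists with the preset correlation and no probe set. Each of them keeps 2 arrays of 1 label together, so part of the labelled difference remains in it. Some of the 16 lists, among them the cardiac muscle, immune and mesothelial lists, nonetheless had a lower camera p in another split. Fry, which tests a list's own genes without comparing them with others, called 12 of the 16, all but the airway secretory, mesothelial, cardiac and skeletal muscle lists.

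**Figure D2:**
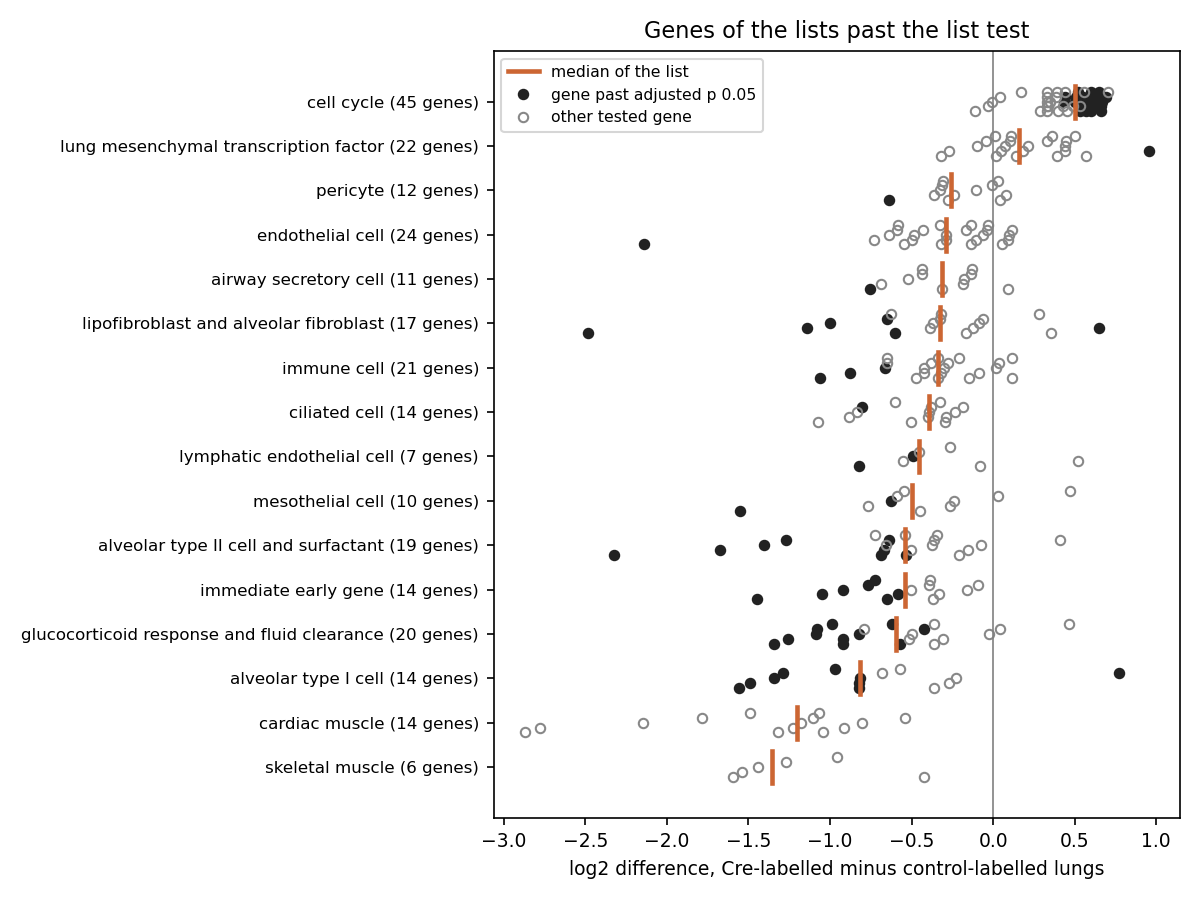
Log2 difference between Cre-labelled and control-labelled lungs (horizontal axis) of every tested gene in the 16 lists past the list test, 1 probe set per gene; filled points passed an adjusted p of 0.05 and orange bars are list medians. The medians ran from -1.36 for skeletal muscle to 0.50 for cell cycle genes; no skeletal or cardiac muscle gene passed on its own.

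Genes of the alveolar epithelium were lower in Cre-labelled lungs. Of 14 alveolar type I cell genes, those of the flat cells of gas exchange, 8 fell, 1 rose and 5 did not pass, with a median log2 difference of -0.82; adjusted over the list alone 10 fell and 1 rose. Examples were the sodium channel subunit gene Scnn1g (-1.34 ± 0.12 SE, limma adjusted p = 0.0023), the water channel gene Aqp5 (-1.49 ± 0.23 SE, adjusted p = 0.012), Clic5 (-0.82 ± 0.11 SE) and Sec14l3 (-0.97 ± 0.13 SE). Rtkn2, Gprc5a, Pdpn and Emp2 also fell, and Igfbp2, an insulin-like growth factor binding protein gene, rose (0.77 ± 0.15 SE, adjusted p = 0.027). The list had an adjusted p of 1.4e-07 in camera, adjusted p = 0.20 with an estimated correlation, and at most 0.011 in its other 20 alternatives.

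Of 19 alveolar type II cell and surfactant genes, 8 fell, none rose and 11 did not pass, with a median log2 difference of -0.54; adjusted over the list alone 13 fell and 1 rose. The largest fall was in S100g, a calcium-binding protein gene (-2.32 ± 0.20 SE, limma adjusted p = 0.0021), and it was 3.20-fold for the fatty acid desaturase gene Scd1 (-1.68 ± 0.14 SE, adjusted p = 0.0021). The surfactant protein genes Sftpb (-1.27 ± 0.20 SE, adjusted p = 0.015), Sftpd (-1.41 ± 0.24 SE) and Sftpa1 (-0.68 ± 0.16 SE, adjusted p = 0.048) fell. The surfactant protein gene Sftpc was tested and did not pass. The lipid transporter gene Abca3 (-0.67 ± 0.10 SE, adjusted p = 0.014), the fatty acid synthase gene Fasn and the transcription factor gene Cebpa fell as well. In the 6 fits without 1 array Sftpb passed in 5, Sftpd and Abca3 in 4, Sftpa1 and Cebpa in 1 and Fasn in 0. The camera adjusted p was 8.8e-09, with adjusted p = 0.24 with an estimated correlation and at most 0.025 in the other 20 alternatives. Cardiac muscle genes were lower as well, with a median of -1.20 and wide differences between arrays of the same group.

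Of 11 airway secretory cell genes 1 fell, the cytochrome P450 gene Cyp2f2 (-0.76 ± 0.16 SE, limma adjusted p = 0.039); the secretoglobin gene Scgb1a1 had a log2 difference of -0.69 ± 0.17 SE (adjusted p = 0.056) and Upk3a one of -0.43 ± 0.15 SE. The list's camera adjusted p was 0.037, adjusted p = 0.38 with an estimated correlation. Its call was also lost without control-labelled replicate 2 or 3, without Cre-labelled replicate 1 or 2, with the cardiac score as a covariate and in fry (adjusted p 0.0042 to 0.38 over all alternatives), and on Cre-labelled replicate 3 the mean of the list lay within the range of the control-labelled arrays. All 14 ciliated cell genes were lower and 1 passed, Tppp3 (-0.81 ± 0.15 SE, adjusted p = 0.021), with a median of -0.40 (-0.66 with the cardiac score as a covariate to -0.23 with the offset of 64) and a camera adjusted p of 1.0e-04, adjusted p = 0.24 with an estimated correlation. Adjusted over the list alone, 2 airway secretory and 4 ciliated cell genes fell. Among 18 genes of epithelial progenitors and lineage the list test was not passed (adjusted p = 0.54), while the transcription factor genes Mycn (0.74 ± 0.16 SE, adjusted p = 0.039) and Foxp2 (0.55 ± 0.11 SE, adjusted p = 0.035) rose; 1 of the other Mycn probe sets had the opposite sign. Adjusted over the list alone 3 of these rose and 3 fell. Sox9 had a log2 difference of 0.57 ± 0.16 SE (adjusted p = 0.079) and Irx1 one of -0.57 ± 0.14 SE (adjusted p = 0.055).

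Cell cycle genes were higher in Cre-labelled lungs. Of 45 tested, 42 had a higher mean, 22 rose past the threshold and none fell; adjusted over the list alone 37 rose. The median log2 difference was 0.50, a 1.41-fold difference. Among the 22 were genes of replication licensing, Mcm4 (0.67 ± 0.11 SE, limma adjusted p = 0.015), Mcm3 (0.65 ± 0.11 SE), Mcm2, Mcm5, Mcm7, Cdc6 and Cdt1, the mitotic genes Ect2 (0.65 ± 0.10 SE, adjusted p = 0.013), Top2a (0.55 ± 0.10 SE), Ttk, Bub1, Bub1b, Mad2l1, Aurka, Kif23, Prc1, Nusap1, Cenpa, Cenpe, Melk and Ccna2, and the proliferation marker gene Mki67 (0.52 ± 0.10 SE, adjusted p = 0.026). None of the 22 passed in all 6 fits without 1 array. Ect2 passed in 5 of them, Mcm4 and Mcm3 in 4, and Mki67 in 0. For the list the camera adjusted p was 3.6e-20, adjusted p = 0.20 with an estimated correlation, and at most 0.011 in the other 20 alternatives. The list also passed in 8 of the other 9 splits, with an adjusted p of 2.7e-10 at the lowest.

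Genes of glucocorticoid response and of the clearance of lung fluid were lower. Of 20 tested, 11 fell, none rose and 9 did not pass; adjusted over the list alone 17 fell, and the median log2 difference was -0.60. All 3 subunits of the epithelial sodium channel fell, Scnn1a (-1.08 ± 0.12 SE, limma adjusted p = 0.0049), Scnn1b (-1.09 ± 0.15 SE, adjusted p = 0.0090) and Scnn1g, which is also in the alveolar type I list. The glucocorticoid-activating enzyme gene Hsd11b1 (-1.25 ± 0.22 SE), the metallothionein genes Mt1 (-0.99 ± 0.13 SE) and Mt2, the sodium pump subunit gene Atp1b1, and Fkbp5, Per1, Errfi1 and Dusp1 also fell. The 3 sodium channel genes, Mt1 and Dusp1 passed in all 6 fits without 1 array. Mt2 and Atp1b1 passed in 4 of these fits, Hsd11b1 in 2, Per1 and Errfi1 in 1 and Fkbp5 in 0. The camera adjusted p was 1.9e-11, adjusted p = 0.20 with an estimated correlation and at most 0.0080 in the other 20 alternatives. Of 14 immediate early genes, which respond within minutes to stimulation and handling, all had a lower mean and 7 fell; adjusted over the list alone 10 fell. Fos fell by 1.44 on the log2 scale (SE 0.20, adjusted p = 0.0086), Ier3 by 1.05 and Dusp1, shared with the list before, by 0.92; Klf2, Klf4, Zfp36 and Ccn1 fell too. The list's camera adjusted p was 7.5e-08, adjusted p = 0.20 with an estimated correlation.

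Mesenchymal genes moved in both directions. Of 17 lipofibroblast and alveolar fibroblast genes 5 fell, 1 rose and 11 did not pass; adjusted over the list alone 7 fell and 1 rose. The fatty acid receptor gene Cd36 (-1.14 ± 0.12 SE, limma adjusted p = 0.0039), Inmt, the amino acid transporter gene Slc7a10, Limch1 and Npnt fell, and the Wnt ligand gene Wnt2 rose (0.65 ± 0.09 SE, adjusted p = 0.0085). The camera adjusted p was 0.0018, adjusted p = 0.28 with an estimated correlation. Among 37 extracellular matrix genes 5 fell and 2 rose, without a shift of the list (adjusted p = 0.17), which passed without Cre-labelled replicate 3, under quantile normalization and with the mean of a gene's probe sets (adjusted p 0.016 to 0.87 over all alternatives); adjusted over the list alone 10 fell and 5 rose. The 5 were the elastin gene Eln (-1.19 ± 0.12 SE, adjusted p = 0.0039), Fbln5 (-0.88 ± 0.10 SE, adjusted p = 0.0044), Mfap2 (-0.58 ± 0.10 SE), Tnc and Npnt. The proteoglycan gene Vcan (1.07 ± 0.13 SE, adjusted p = 0.0068) and the fibrillin gene Fbn2 (0.66 ± 0.11 SE) rose. Of 18 smooth muscle and myofibroblast genes Synpo2 rose and Hhip and Pdlim3 fell, again without a shift of the list (adjusted p = 0.88). Of 12 pericyte genes Higd1b fell (-0.64 ± 0.11 SE); the list's camera adjusted p was 0.040, adjusted p = 0.24 with an estimated correlation, and the call was lost in 8 of 21 alternatives, among them those without control-labelled replicate 1 or 2 or Cre-labelled replicate 1 or 2 (adjusted p 0.020 to 0.37). Of 22 lung mesenchymal transcription factor genes 18 were higher and 1 rose, Hoxb5 (0.95 ± 0.14 SE, adjusted p = 0.012); the camera adjusted p was 0.011, adjusted p = 0.24 with an estimated correlation. Adjusted over the list alone, 2 transcription factor genes rose, 1 pericyte gene fell, and 3 smooth muscle genes rose and 3 fell.

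Of the lists of other resident cells, the endothelial, immune, mesothelial and lymphatic lists passed as lower and the erythroid list did not pass. Of 24 endothelial cell genes 20 had a lower mean and 1 fell, Car4 (-2.14 ± 0.22 SE, limma adjusted p = 0.0039), which marks alveolar capillaries; adjusted over the list alone 10 fell. The values of Ramp2 (-0.59 ± 0.14 SE), Icam2 (-0.55 ± 0.14 SE) and Emcn (-0.59 ± 0.15 SE) lay just short of the threshold (adjusted p 0.052, 0.061 and 0.066). The endothelial list had a camera adjusted p of 4.2e-04, adjusted p = 0.26 with an estimated correlation. Of 21 immune cell genes 3 fell. These were the lysozyme gene Lyz2 (-0.88 ± 0.14 SE, adjusted p = 0.015) and the neutrophil genes S100a8 and Ngp. In the 6 fits without 1 array Lyz2 passed in 3, Ngp in 1 and S100a8 in 0. The immune list's camera adjusted p was 3.4e-04, adjusted p = 0.26 with an estimated correlation. Of 10 mesothelial cell genes Msln, the gene of mesothelin, fell 2.93-fold (-1.55 ± 0.17 SE, adjusted p = 0.0049) and Krt19 fell (-0.63 ± 0.14 SE); the list's adjusted p was 0.0046, adjusted p = 0.38 with an estimated correlation. The mean of the mesothelial list was lower on Cre-labelled replicates 1 and 2 (-0.76 and -0.52 from the control-labelled mean), while replicate 3 (-0.08) lay within the range of the control-labelled arrays. Of 7 lymphatic endothelial cell genes Pdpn, which is also in the alveolar type I list, and Lyve1 fell. Lyve1 passed in 0 of the 6 fits without 1 array, and Pdpn in 2. The lymphatic list's camera adjusted p was 0.040, adjusted p = 0.24 with an estimated correlation. Its call was lost in 7 of 21 alternatives, among them those without control-labelled replicate 1 or 2 or Cre-labelled replicate 1 or 2. Over all alternatives its adjusted p ran from 0.011 to 0.24. With the cardiac score as a covariate the immune, mesothelial and lymphatic calls were lost. Adjusted over the list alone, 5 immune, 4 mesothelial and 5 lymphatic genes fell and 1 lymphatic gene rose. None of 10 erythroid genes passed, over all genes or adjusted over the list alone; the list (adjusted p = 0.18) passed with median scaling alone (adjusted p 0.048 to 0.90 over its alternatives).

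Lists of signalling pathways did not shift as wholes, but single members passed the threshold. Of 21 Wnt signalling genes the Wnt amplifier gene Rspo2 (1.42 ± 0.17 SE, limma adjusted p = 0.0056), Lef1, a transcription factor of the pathway (1.06 ± 0.21 SE, adjusted p = 0.030), and Wnt2 rose, and Dkk3 (-0.70 ± 0.16 SE) and the receptor gene Fzd4 (-0.44 ± 0.10 SE) fell. The list did not pass (adjusted p = 0.48) except in fry (adjusted p 0.049 to 0.67 over its alternatives). Of 25 TGF-beta and BMP signalling genes Bmper (0.77 ± 0.11 SE, adjusted p = 0.0093) and Bmp5 (0.43 ± 0.09 SE) rose and Ccn2 fell (-0.83 ± 0.18 SE; list adjusted p = 0.54). Of 22 FGF and hedgehog signalling genes Gli3, a hedgehog transcription factor gene (0.89 ± 0.13 SE, adjusted p = 0.0095), rose, and Fgf1, Spry1 and Hhip fell (list adjusted p = 0.66). Of 23 growth factor genes Igfbp2 and Pdgfc rose and Igfbp6 (-1.73 ± 0.15 SE, adjusted p = 0.0021), Igfbp7 (-0.87 ± 0.13 SE) and Vegfd (-0.45 ± 0.10 SE) fell (list adjusted p = 0.83). Rspo2, Wnt2, Bmper, Gli3 and Igfbp6 passed in all 6 fits without 1 array, Igfbp7 in 4 and Igfbp2 in 2. Lef1, Dkk3, Ccn2, Spry1 and Pdgfc passed in 1 of these fits, and Fzd4, Bmp5, Fgf1, Hhip and Vegfd in 0. With p adjusted over the list alone, 4 Wnt genes rose and 3 fell, 2 TGF-beta and BMP genes rose and 1 fell, 4 FGF and hedgehog genes rose and 5 fell, and 4 growth factor genes rose and 5 fell. None of 15 hypoxia and glycolysis genes passed by either adjustment (list adjusted p = 0.76); Ndrg1 was at -0.54 ± 0.17 SE.

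Markers of neighbouring tissues varied between arrays. All 14 cardiac muscle genes had a lower mean in Cre-labelled lungs, with a median log2 difference of -1.20, but none passed the threshold, and 1 did adjusted over the list alone. The atrial myosin gene Myl7 read 11.43, 10.95 and 9.71 in control-labelled and 9.08, 9.42 and 10.38 in Cre-labelled lungs, so the groups overlapped. The list's camera adjusted p was 3.4e-05, adjusted p = 0.38 with an estimated correlation, and 0.0012 without control-labelled replicate 1, and its median ran from -1.66 to 0.0756 over the alternatives. Skeletal muscle genes were high in control-labelled replicate 1 alone, where Acta1 read 9.95 against 5.53 to 5.84 on the other 5 arrays; the list of 6 genes (median -1.36, camera adjusted p = 0.036, adjusted p = 0.55 with an estimated correlation) had a median of -0.25 and an adjusted p of 0.23 without that array. It also lost its call without Cre-labelled replicate 1 or 2 (adjusted p 3.7e-04 to 0.98 over all alternatives). The albumin gene Alb read 8.69 in control-labelled replicate 2 and 4.36 in control-labelled replicate 1. None of 8 cartilage genes passed (list adjusted p = 0.54; 2 rose and 1 fell adjusted over the list alone), and Col9a1 was at 1.34 ± 0.33 SE (limma adjusted p = 0.060). Too few genes were tested for a list test of neuroendocrine cells (3), thymus and lymphocytes (2), squamous epithelium (4), peripheral nerve (4) and liver (4); in these, the keratin gene Krt15 (about 2-fold lower, SE 0.18 on the log2 scale, adjusted p = 0.020) and Stmn2 (-0.62 ± 0.12 SE, adjusted p = 0.027) fell. In these lists, adjusted over the list alone, 1 neuroendocrine, 1 squamous and 2 nerve genes fell, 1 nerve gene rose, and none of the thymus and liver genes passed. Xist and the Y-linked gene Eif2s3y marked 1 female lung in each group, control-labelled replicate 1 and Cre-labelled replicate 2.

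**Figure D3:**
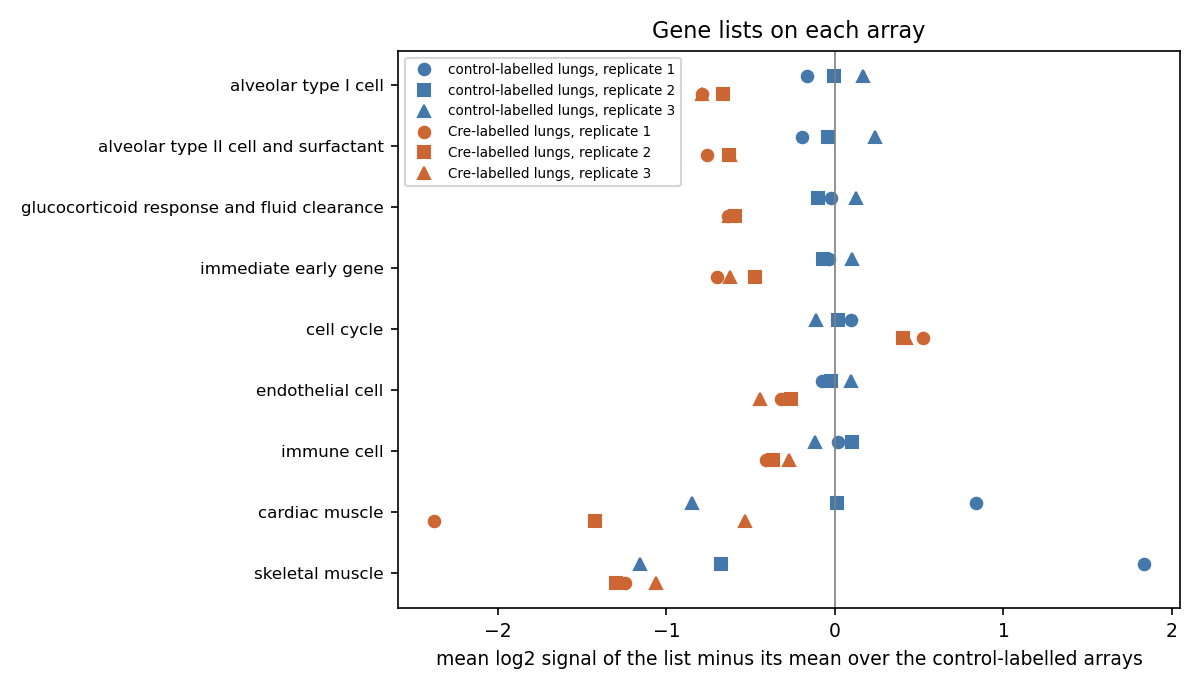
Mean log2 signal of 9 gene lists on each array (horizontal axis), as the difference from the list's mean over the 3 control-labelled arrays; colour gives the labelled group and marker shape the replicate. The groups were apart for alveolar, glucocorticoid, immediate early, cell cycle, endothelial and immune genes, whereas cardiac muscle genes overlapped and skeletal muscle genes were high on control-labelled replicate 1 alone, at 1.84.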

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

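Alternatives with covariates were chosen after seeing the data. The main count of 963 probe sets past the threshold stayed within 1.5 times under quantile normalization (1270), median scaling (647), offsets of 1 and 64, no filter, the stricter filter, array weights, the 1.5-fold minimum and the 3' minus 5' covariate. It was 171 without an intensity trend, 2120 at an adjusted p of 0.10, 587 with sex as a covariate and 215 with the cardiac score as a covariate, and it ran from 314 to 495 with 1 array left out, where fewer arrays were fitted. With 1 probe set per gene tested, 1150 of 12826 genes passed, against 636 genes in the main fit. The cause of these differences was not tested, except that the looser threshold admits more by its construction. No probe set called in both the main and an alternative fit turned its direction. Of the 120 named genes past the threshold, none changed sign in any alternative, 36 stayed past it in all 6 fits without 1 array, 29 did without an intensity trend, 30 with the cardiac score as a covariate, 82 with sex as a covariate and 80 with median scaling, and 19 did under every alternative. With the replicate block 1309 probe sets passed, 902 of them among the 963; deviations of arrays of the same number from their group means correlated at -0.01, 0.20 and 0.14, 3 of the 6 arrays correlated best with their own number, and the numbers were not taken as pairs. The median difference of all tested probe sets moved by less than 0.1 under every scaling.

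The 16 gene lists past the list test became 0 with an estimated correlation and 9 with the cardiac score as a covariate; other alternatives gave 12 to 17. Both the alveolar lists, cell cycle, glucocorticoid, immediate early, ciliated, endothelial, lipofibroblast and transcription factor lists, 9 in all, passed under every alternative but the estimated correlation. The cardiac list turned to a median of 0.0756 (adjusted p = 0.82, with 8.2e-09 to 0.82 over its alternatives) with its own mean as the covariate, which follows from that construction. The brightest Nfib probe set stayed higher, by a log2 difference of 0.96 to 1.19, past the threshold in all 18 alternatives; of the other 4 that rose, 2 passed in all 18, 1 in 17 and 1 in 9, and the tested one that did not rise was lower in all 18 (-0.23 to -0.03) without passing. Values near the floor limit what can be said of dim genes, among them 4 of the 12 largest falls and 3 of the 12 largest rises.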

Other observations

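Gene families were defined after seeing the data by the letters of the symbol before its first digit, with at least 8 tested genes. They partly overlap the fixed lists, since some Mcm and Kif genes are in the cell cycle list and some Klf genes in other lists. Of 208 families, 10 moved in camera with a preset correlation, 7 higher and 3 lower in Cre-labelled lungs, and none held with an estimated correlation (adjusted p at least 0.79). All 10 Mcm genes, of which several are in the cell cycle list, were higher (median log2 difference 0.61, 6 rose, adjusted p = 6.6e-06). Nucleoporin genes (Nup, 17 of 18 higher, median 0.26, none past the threshold singly, adjusted p = 6.8e-04), Rad genes of DNA repair (14 of 15 higher, median 0.41, 3 rose, adjusted p = 0.0022), centrosomal Cep genes (29 of 36 higher, median 0.19), kinesin genes (Kif, 21 of 30 higher, 5 rose) and zinc finger genes (Zfp, 224 of 301 higher, median 0.16, 8 rose and 1 fell) were higher as well, as were all 12 protocadherin beta genes (Pcdhb, median 0.47, none past the threshold singly, adjusted p = 0.015). Lower were the Krüppel-like factor genes (Klf, 11 of 15 lower, median -0.31, 4 fell, adjusted p = 0.0097), which overlap the immediate early list, the Atp genes, among them subunits of ion pumps and of ATP synthase (50 of 66 lower, median -0.12, 5 fell, adjusted p = 0.0072), and the cilium-associated Cfap genes (16 of 22 lower, median -0.27, 1 fell, adjusted p = 0.026). None of the medians of these 10 families turned in sign under quantile normalization, median scaling or either offset. Without Cre-labelled replicate 1 the calls of the Atp, Cfap, Kif and Pcdhb families were lost, and without control-labelled replicate 2 that of the Cfap family. The cardiac score as a covariate ended the calls of the Atp, Cep, Cfap, Klf and Pcdhb families, the absence of a filter that of Pcdhb, and the offset of 64 and the stricter filter that of Cfap.

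The tests of the Nfib pattern and of the cardiac pattern were chosen only after their results were seen; those of the alveolar pattern and of other splits were written before. Nfib signal was about 2-fold higher in lungs labelled as carrying the deleting Cre. Array scaling as the cause is argued against by quantile normalization, after which the log2 difference was 1.04. Only part of the transcript may have risen, since the brightest probe set exceeded the lowest tested one, picked after its value was seen, in log2 difference by 1.16 (interval of 2 SE either side, 0.75 to 1.57); the position of either probe set in the gene was not known here. An exchange of the labels of whole groups cannot be told apart from a rise of Nfib RNA that lies outside the deleted part or in other cells, because the 5 tested probe sets past the threshold that were higher would be so under either and all 3 arrays of each group moved together.

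Alveolar genes were lower and cell cycle genes higher in Cre-labelled lungs. A smaller share of epithelial cells as the whole cause is argued against by 19 genes of all epithelial cells, from a list written before this test although the values of 5 of them had been seen by then, as had the 3' and 5' signals of the arrays before the next test. Their median log2 difference was -0.28 (17 lower, 1 past the threshold) against -0.66 for the 33 alveolar genes, a difference of 0.38 (95% bootstrap interval over genes 0.16 to 0.55). The interval resamples genes measured on the same arrays, so it does not measure the spread between animals. A smaller share of epithelial cells could still account for part of the fall. A smaller share of alveolar cells among the epithelial cells was not tested. In the fit with the 3' minus 5' control signal as a covariate the alveolar median was -0.68 (95% bootstrap interval over genes -0.80 to -0.53). That signal read 0.09, 0.08 and 0.23 on control-labelled and 0.04, 0.06 and 0.45 on Cre-labelled arrays. Because it overlapped between the groups, it could change the group difference only a little as a covariate. The alveolar fall thus did not follow this signal, which argues against RNA quality only as the signal measures it. Other forms of RNA damage were not tested. Less advanced epithelial differentiation, a general delay of development or a difference in the age of litters was not tested and stays open.

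Cardiac muscle genes may differ because the samples held unequal amounts of heart or of cardiac muscle around pulmonary veins. The 14 genes deviated together from their group means, with a median pairwise correlation of 0.79 over the 6 arrays, against at most 0.51 in 1000 random sets of 14 genes. The random sets were not markers of 1 tissue, so they show only that the cardiac genes varied together more than unrelated genes. A difference between the genotypes stays open: the mean cardiac score gave an exact permutation p of 0.20, two-sided, where 0.10 is the smallest possible, so this design cannot decide. The muscle gene Pgam2, among the 12 largest falls, was called in these same arrays.

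The splits of the 6 arrays into 3 and 3 number 10, the real one included, too few for a share under 0.05. The real split gave 963 probe sets and the highest of the other 9 gave 0 (1 of 10 splits as large); at an unadjusted p of 0.05 the real split gave 5262 and the highest other 1659. For lists, the real split gave 16 and the highest other 13 (1 of 10 splits as large). Each other split puts 2 arrays of 1 label with 1 of the other, so part of the labelled difference remains in it and its calls do not measure how often the list test errs. Cell cycle, glucocorticoid, both alveolar, immediate early and endothelial lists had their lowest p in the real split. The other called lists had a camera p at least as low in another split. For cardiac muscle the lowest camera adjusted p of another split was 1.2e-27, against 3.4e-05 in the real one. It was 1.5e-06 against 3.4e-04 for immune genes and 6.0e-06 against 0.0046 for mesothelial genes. The labelled difference left in a split does not by itself account for these lower values.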
